A study of Mus musculus with 12 samples.

How the data were processed

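Per the labels, RNA was sequenced from mouse skin in 12 libraries. The deposited table holds counts, whole read numbers per Entrez Gene ID with no normalization, in 18 columns. The labels match 12 columns to the samples, 1 column per library, and the other 6 columns match no sample and were not used. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat, DESeq and the build mm10. The counting program, the annotation and the strand setting are not given in the sources used here. Of 23469 gene IDs, 23372 matched a symbol in the mouse annotation. The 97 without a symbol held 7.57% to 15.8% of a library's counts, and the most abundant of them moved with Mup2 (correlation of log2 CPM over the 12 libraries 0.9998). Total counts ran from 6705396 to 12933436 per library, and the report gives each. In 76 tested genes the counts equal those of another gene in every library, and 6 of these are list members (Sprr2a1 and Sprr2a2, Hbb-b1 and Hbb-b2, Hba-a1 and Hba-a2).

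Groups and replicate numbers follow the labels. Genes were kept by filterByExpr, scaled by TMM (factors 0.647 to 1.28) and fitted with the quasi-likelihood model of edgeR 4.0.16 (glmQLFit with robust on, R 4.3.3), with 1 coefficient per group. The common dispersion was 0.182. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15341 genes tested. Standard errors of log2 fold changes come from the same fit. The 5 planned comparisons were ASP against SAL in each genotype, labelled-null against wild type under each treatment, and the interaction. These comparisons, the gene lists, the rule for named genes and the other settings tried were fixed before the data were examined. The exceptions are the 2 averaged comparisons and the settings without both libraries farthest from the rest or without Mup genes and IDs lacking a symbol, which were chosen after seeing the data. Group means in the report are TMM-scaled CPM. Genotype differences of the Serpinb3 paralogs were tested with a two-sided exact permutation test over 924 splits of 6 against 6 libraries on log2(CPM + 0.5). With 3 libraries against 3 the smallest p of such a test is 0.1, so the comparisons of groups rest on the model fitted across genes.

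Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, adjusted over the 29 lists of a comparison. For labelled-null against wild type under SAL, the estimates ran from -0.0794 (B and plasma cell markers) to 0.726 (red blood cell transcripts). Only the B cell and T cell lists (0.00269) lay below the preset there. Where the members of a list move together more than the preset assumes, its p-values are too small. A list needed at least 3 tested members. Of 738 listed genes, 731 were in the table. The filter on low counts left fewer to test in some lists. It left 13 of 45 hair shaft genes, 14 of 35 type 17 genes and 8 of 18 neutrophil markers. Of B and plasma cell markers it left 4 of 12, and of eosinophil and basophil markers 5 of 11. It left 24 of 35 type 2 genes, 28 of 36 epidermal stress genes, 44 of 49 cornified envelope genes and 7 of 10 red blood cell transcripts. Further lists lost members too, and only some were tested in full, such as barrier lipid synthesis (31 of 31). Medians and counts of members cover the tested members only. The lists, chosen from textbook knowledge, were Serpinb3 locus paralogs, other clade B serpins of the epidermis, type 2 cytokines with alarmins and their targets, type 17 and antimicrobial genes, proinflammatory cytokines and myeloid chemokines, interferon response, epidermal stress and wound response, cornified envelope and terminal differentiation, epidermal barrier lipid synthesis, tight junction and adhesion, cell cycle and mitosis, proteases and inhibitors of the skin, neutrophil markers, monocyte and macrophage markers, eosinophil and basophil markers, mast cell markers, T cell and innate lymphoid markers, B and plasma cell markers, dendritic and Langerhans cell markers, hair shaft and inner root sheath, hair follicle stem cell and outer root sheath, sebaceous gland, melanocyte markers, skeletal muscle, adipocyte, fibroblast and extracellular matrix, endothelial cell markers, red blood cell transcripts and immediate early and heat shock. For each comparison the named genes were Serpinb3a, Serpinb3b, Serpinb3c and Serpinb3d, up to 10 called genes per direction with a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members of each list described with the smallest p, and, where fewer than 5 genes passed, the 5 with the smallest p. Genes outside this rule are named as chosen after their values were seen, and some genes within it are not reported here.

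The alternatives were RLE size factors, upper-quartile scaling, no filter on low counts, a filter of 2 CPM in 3 libraries, robust off, the replicate number as a block, only the 6 libraries compared, DESeq2 1.42.0, limma-voom with quality weights, and each library left out in turn. The correlation of gene residuals between libraries with the same replicate number was over 0.1 in 5 of 18 pairs, with a median of -0.0113 against 0.00484 for other pairs, so the samples were not treated as paired. No pair of libraries was identical. The fit was tested on simulated data with 200 changed genes and the same group sizes. It recovered 8%, 46%, 86% and 96% of genes changed 2, 4, 8 and 16 times for ASP in wild type, with 4.84% false calls. For the interaction it recovered 0%, 14%, 54% and 70%, and for labelled-null against wild type over both treatments 12%, 72%, 88% and 96%. Changes of 2 times were therefore mostly out of reach at this depth and spread. The simulation was run once per comparison and drew each gene independently, without outlying libraries, so recovery in the real data may be lower. Between genotypes under SAL it recovered 86% of genes changed 8 times. Yet Cyp2g1 (log2 fold change 3.09) and Serpinb3a (3.66) did not pass there in edgeR, so larger changes could be missed too.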

Results

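RNA from mouse skin was sequenced in 12 libraries that fall into 4 groups of 3. Wild-type BALB/c mice and mice labelled Serpinb3a-null had their backs shaved on day 0 and carried a gauze patch from day 1 to day 4, and skin was collected on day 5. In the ASP groups the patch held 200 µg of an extract of Aspergillus fumigatus, a mould and a common source of airborne allergen. The other groups are marked SAL, which the labels do not expand. The labels name the other genotype in 3 ways: a knockout of SCCA2 (a human SERPINB serpin) in the titles, a Serpinb3a transgene in the genotype field and a Serpinb3a null in the design text. Since Serpinb3a was counted higher, not lower, in the libraries of that genotype, the animals are called labelled-null throughout, and each direction between genotypes is drawn by that label. The labels do not say whether the libraries of a group come from separate animals, so the p-values measure only the spread between samples.

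The wild-type SAL libraries held 12659425, 9183009 and 10897803 counts in replicates 1, 2 and 3, and the wild-type ASP libraries held 9559632, 8390211 and 9030721. The labelled-null SAL libraries held 6705396, 12933436 and 12009435, and the labelled-null ASP libraries held 10456277, 11268730 and 8115038. Malat1, a nuclear noncoding RNA, averaged 5.56% of counts and Ttn, the giant spring protein of striated muscle, 3.74%. The genes with a Mup symbol, for major urinary proteins, are near-identical copies whose reads cannot be assigned with certainty. They held 8.43% to 39.0% of a library. Krt14, the keratin of basal epidermis, ranged from 134 to 403 counts-per-million (CPM) of the unscaled total. Tchh, a protein of the inner root sheath of hair, stood at 165 on that scale in wild-type SAL replicate 1 and at 5.88 or less in the other 11 libraries. Spearman correlations between libraries ran from 0.854 to 0.965, with a median of 0.933 within groups and 0.928 between groups. Wild-type ASP replicate 3 (median correlation with the others 0.895), labelled-null SAL replicate 1 (0.899) and wild-type ASP replicate 2 (0.902) stood farthest from the rest. The coefficient of biological variation shared by all genes was 0.427.

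Serpinb3a, a clade B serpin that inhibits proteases, was counted at higher levels in the labelled-null libraries than in wild type. It lies on chromosome 1 from 107045587 to 107052303 (mm10). Its mean was 4.71 ± 3.05 CPM scaled by TMM (trimmed mean of M-values) in labelled-null and 0.685 ± 0.409 in wild type (SD, n = 6 per genotype, two-sided exact permutation p = 0.00217, adjusted over the 4 paralogs 0.00433). It was higher in 6 of 6 labelled-null libraries, the lowest at 1.74 CPM, than in any wild-type library, the highest at 1.40. The group means were 0.583 ± 0.242 CPM in wild-type SAL, 0.788 ± 0.573 in wild-type ASP, 7.41 ± 1.12 in labelled-null SAL and 2.01 ± 0.283 in labelled-null ASP (SD, n = 3). The neighbouring paralog Serpinb3d was higher in labelled-null libraries too, at 1.75 ± 0.861 against 0.189 ± 0.0785 CPM (n = 6, exact p = 0.00217, adjusted 0.00433). Serpinb3b was lower, at 7.31 ± 0.641 against 19.5 ± 10.96 CPM (n = 6, exact p = 0.0260, adjusted 0.0346). Serpinb3c stood at 1.43 ± 0.542 against 2.48 ± 1.13 CPM (n = 6, exact p = 0.0931). Summed over the 4 paralogs, the means were 15.2 ± 3.77 and 22.8 ± 12.2 CPM (n = 6, exact p = 0.310). Between 4.97% and 14.3% of the 50-base stretches of each paralog's transcripts also occur in another of the 4, so the value of each paralog is uncertain. Wild-type libraries held 2 to 15 counts of Serpinb3a and 1 to 3 of Serpinb3d.

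**Figure D1:**
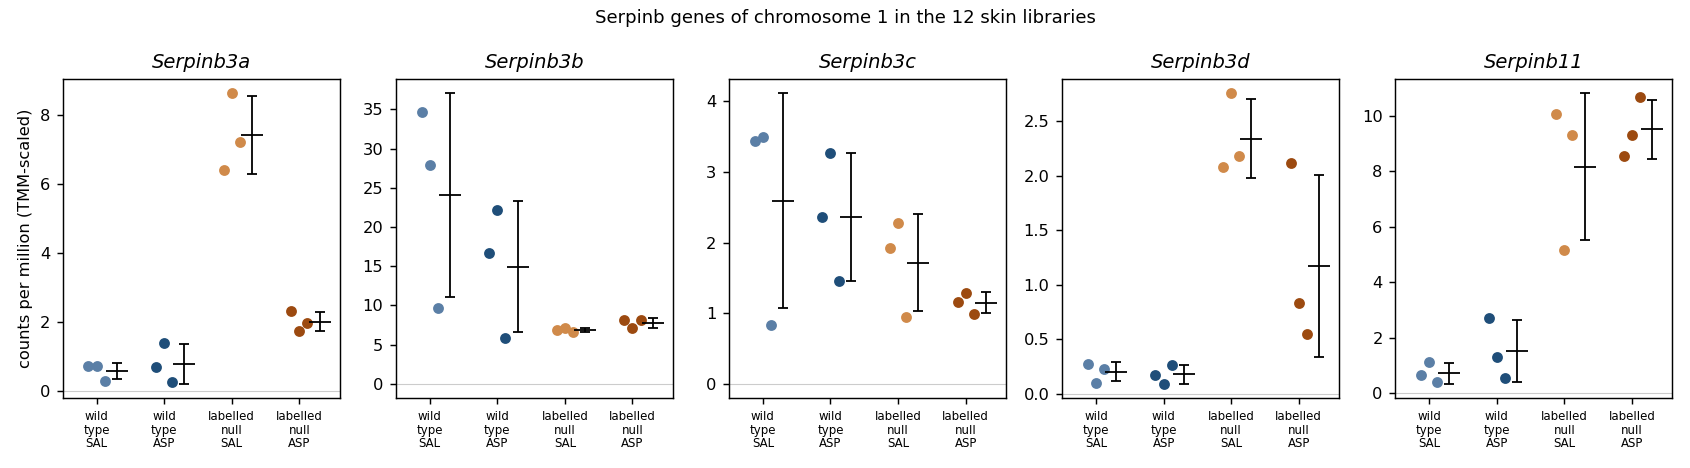
TMM-scaled CPM of the Serpinb3 paralogs and Serpinb11 in the 12 libraries by genotype and treatment, 1 point per library, with bars for the mean ± SD of each group of 3. Serpinb3a, Serpinb3d and Serpinb11 do not overlap between the labelled-null and wild-type libraries.

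ASP was compared with SAL in wild-type skin to show what the extract does to normal skin. Monocyte and macrophage markers stood higher under ASP, with a median log2 fold change of 0.49 over 24 genes, 18 of them positive. So did type 2 genes, a list of cytokines, alarmins and targets of the allergic response (0.51 over the 24 of 35 tested, 19 positive). The type 2 members named below include no gene for an interleukin. Dendritic and Langerhans cell markers stood higher as well (0.37 over 22, 17 positive). Genes of the hair shaft and inner root sheath stood lower (-1.39 over 13, 0 positive), as did skeletal muscle genes (-0.36 over 29, 7 positive) and immediate early and heat shock genes, which respond to tissue handling (-0.30 over 20, 8 positive). These 6 of 29 lists passed camera, a test of a list against all other genes, at its preset correlation. The hair, type 2, dendritic cell and immediate early lists had adjusted p = 5.04e-05, 0.0108, 0.0108 and 0.0108 in that order, and adjusted p = 0.506 with an estimated correlation. The monocyte list had adjusted p = 0.00402, and adjusted p = 0.650 with an estimated correlation. The muscle list had adjusted p = 0.0293, and adjusted p = 0.876 with an estimated correlation. Ccl24, a chemokine that attracts eosinophils, averaged 0.184 and 2.24 CPM under SAL and ASP (log2 fold change 3.56 ± 0.98 SE). Clec10a, a lectin of macrophages and dendritic cells, averaged 5.21 and 14.5 (1.48 ± 0.53), Retnla, a product of alternatively activated macrophages, 20.6 and 54.0, and Il1rl1, the receptor for IL-33, 4.94 and 9.61. The scavenger receptor Cd163 averaged 14.5 and 30.5 CPM (1.07 ± 0.42), the chemokine receptor Ccr2 24.8 and 49.5, the adaptor Tyrobp 5.57 and 14.3, and the lysozyme Lyz1, which shares reads with Lyz2, 71.2 and 130.4. Cd83, a marker of mature dendritic cells, averaged 1.29 and 6.87 CPM (2.39 ± 0.81), and the class II gene H2-Eb1 19.97 and 40.1 (1.01 ± 0.43). Clec9a averaged 1.18 and 3.06 and Batf3 0.432 and 1.42, both genes of cross-presenting dendritic cells. Of these 3 lists, 0, 0 and 0 genes passed adjusted over the list alone, and 0 over all genes.

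Of the lists that stood lower under ASP in wild type, 3 hair genes passed adjusted over the list alone and 0 over all genes. Tchh averaged 65.5 ± 107 and 1.11 ± 0.736 CPM under SAL and ASP (SD, n = 3, log2 fold change -5.81 ± 1.39 SE). Its SAL mean rests on replicate 1, at 165 CPM of the unscaled total against 5.88 and 2.57 in replicates 2 and 3. The keratin Krt27 averaged 14.8 and 0.669 (-4.39 ± 1.22) and the keratin-associated Krtap3-3 3.52 and 0.268 (-3.57 ± 1.23). Dsg4, a desmosomal cadherin of hair, averaged 2.64 and 0.177 and did not pass. Nr4a1, a nuclear receptor induced within minutes, averaged 17.9 and 5.36 CPM (-1.73 ± 0.46) and was the 1 immediate early gene that passed adjusted over the list alone. The heat shock gene Hsph1 averaged 87.4 and 52.7, Zfp36, which marks cytokine mRNA for decay, 66.2 and 34.3, and the transcription factor Egr2 24.6 and 13.8. In muscle, the creatine kinase Ckm averaged 1702 and 809 CPM, Mybpc2 243 and 126 and Actn3 446 and 215, while the slow-fibre troponin Tnni1 averaged 0.151 and 0.917. Muscle had 0 genes adjusted over the list alone, and the immediate early and muscle lists had 0 over all genes. Without wild-type SAL replicate 1, the calls for type 2 (adjusted p = 0.113), monocyte (0.131), dendritic cell (0.131), hair (0.113), muscle (0.520) and immediate early (0.113) ended. The calls for type 2 (adjusted p = 0.297), monocyte (0.297), dendritic cell (0.0801), muscle (0.297) and immediate early (0.174) ended without wild-type ASP replicate 2. Leaving out wild-type ASP replicate 3 ended the calls for type 2 (adjusted p = 0.0591) and dendritic cell (0.125). Without wild-type SAL replicate 3, the call for muscle (adjusted p = 0.705, with the direction turned) ended. The call for muscle (adjusted p = 0.0834) ended without wild-type ASP replicate 1. Without both libraries farthest from the rest, the type 2 list had adjusted p = 0.0660 and the dendritic cell list 0.113.

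Over all 15341 genes, edgeR called 0 higher and 0 lower for ASP in wild type, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 440 genes higher and 287 lower, 727 in all, where 5% of the genes tested is 767. DESeq2 called 1 higher (Gm15093, named after its values were seen) and 1 lower (Rps6ka2), and limma-voom called 0 and 0. The 5 genes with the smallest p did not pass in edgeR. Rps6ka2, a ribosomal S6 kinase, averaged 31.8 ± 10.1 and 8.97 ± 3.28 CPM under SAL and ASP (SD, n = 3, log2 fold change -1.82 ± 0.38 SE). Taf1b, a factor for ribosomal RNA transcription, averaged 7.91 ± 0.452 and 26.0 ± 15.5 CPM, and Sdc4, a cell-surface proteoglycan, 20.3 ± 6.79 and 62.5 ± 43.2. The proton pump subunit Atp6v0e averaged 9.53 ± 2.26 and 60.6 ± 70.7 CPM, with 142 in wild-type ASP replicate 3, and Tchh was the other. The Serpinb3 paralogs had log2 fold changes of 0.47 ± 0.66 (Serpinb3a), -0.69 ± 0.48 (Serpinb3b), -0.12 ± 0.67 (Serpinb3c) and -0.23 ± 0.98 (Serpinb3d). The groups did not overlap for 6.79% of genes, and chance gives 10%.

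**Figure D2:**
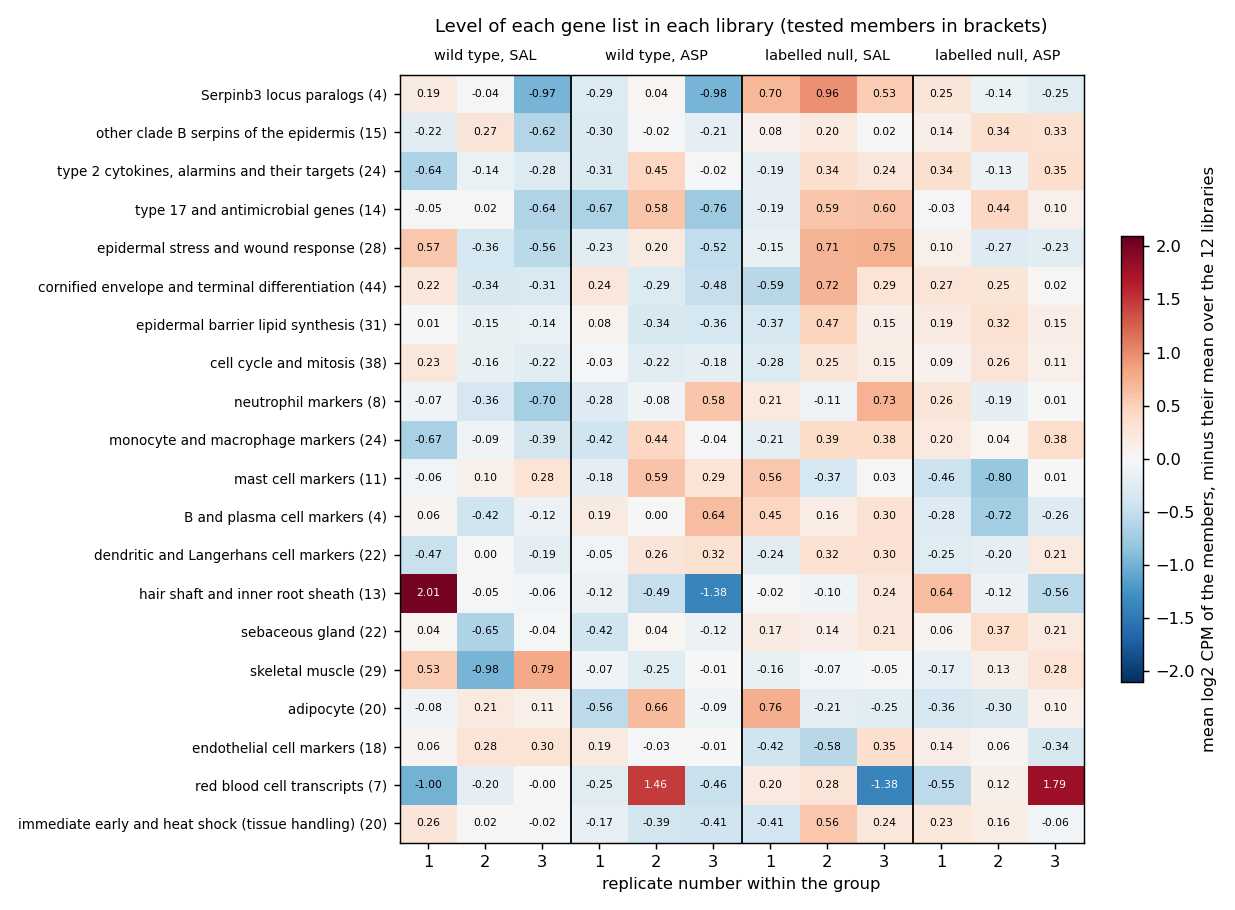
Level of each gene list that passed camera in any of the 5 planned comparisons (vertical axis) in each library (horizontal axis, by group), as the mean log2 CPM of its members minus their mean over the 12 libraries. The hair list stands at 2.01 in wild-type SAL replicate 1, and red blood cell transcripts at 1.46 in wild-type ASP replicate 2 and 1.79 in labelled-null ASP replicate 3.

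The same treatments were compared in labelled-null skin to show what the extract does there. Epidermal stress and wound genes stood lower under ASP, with a median log2 fold change of -0.52 over 28 genes, 5 of them positive. Adipocyte genes stood lower (-0.38 over 20, 6 positive) and red blood cell transcripts higher (1.09 over 7, 7 positive). The 7 include Hbb-b1 with Hbb-b2 and Hba-a1 with Hba-a2, each pair identical in counts, and each gene was counted separately. These 3 of 29 lists passed camera at its preset correlation. The epidermal stress list had adjusted p = 0.00657, and adjusted p = 0.699 with an estimated correlation. The adipocyte and red blood cell lists had each adjusted p = 0.0371, and adjusted p = 0.963 with an estimated correlation. Stfa3, a stefin that inhibits cysteine proteases and has close copies, averaged 44.3 and 6.26 CPM under SAL and ASP (-2.81 ± 0.97 SE), with 111, 15.0 and 6.64 in SAL replicates 1, 2 and 3. Sprr2b, a small proline-rich protein of the cornified envelope, averaged 1.47 and 0.183, and Sprr2a1 and Sprr2a2, whose counts are identical in every library, 19.5 and 6.45 each. Plin1, which coats lipid droplets, averaged 351 and 137 CPM (-1.36 ± 0.45), the adipokine Retn 92.3 and 29.3 (-1.66 ± 0.64), the glycerol phosphate dehydrogenase Gpd1 423 and 226 and the triglyceride lipase Pnpla2 170.1 and 105. Alas2, which starts haem synthesis in red cell precursors, averaged 1.79 and 4.75 CPM (1.41 ± 0.60). The beta globins Hbb-b1 and Hbb-b2, identical in counts, averaged 4.92 and 11.2 each and Hbb-bs 6.37 and 13.5. Hbb-bs stood at 34.7 CPM of the unscaled total in wild-type ASP replicate 2 and 33.8 in labelled-null ASP replicate 3, and at 7.81 or less in the other 10 libraries. In these 3 lists 0, 0 and 0 genes passed adjusted over the list alone, and 0 over all genes. Leaving out labelled-null SAL replicate 3 ended the calls for epidermal stress (adjusted p = 0.117) and red blood cell (0.545). Without labelled-null SAL replicate 2, the call for epidermal stress (adjusted p = 0.104) ended. The call for adipocyte (adjusted p = 0.919) ended without labelled-null SAL replicate 1. Leaving out labelled-null ASP replicate 1 ended the call for adipocyte (adjusted p = 0.172). Without labelled-null ASP replicate 2, the call for adipocyte (adjusted p = 0.0985) ended. The call for red blood cell (adjusted p = 0.972) ended without labelled-null ASP replicate 3. With the replicate number as a block, the red blood cell call had adjusted p = 0.0793. Without both libraries farthest from the rest, the adipocyte list had adjusted p = 0.887.

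Over all genes, edgeR called 0 higher and 0 lower for ASP in labelled-null skin, with 237 and 456 at an unadjusted p under 0.05 and a smallest adjusted p of 0.990. DESeq2 called 0 higher and 2 lower (Gsta2 and, named after its values were seen, Gm15093), and limma-voom called 0 and 0. The 5 genes with the smallest p, none of which passed in edgeR, all had lower means under ASP. Dapp1, an adaptor of B cell signalling, averaged 45.5 ± 15.1 and 12.7 ± 3.07 CPM under SAL and ASP (SD, n = 3, -1.84 ± 0.43 SE). Tnfrsf13c, the receptor for the B cell survival factor BAFF, averaged 3.66 ± 2.16 and 0.325 ± 0.153 (-3.47 ± 0.81), and the metalloprotease Adam12 37 ± 9.79 and 14.2 ± 3.80 (-1.38 ± 0.33). The glutathione transferase gene Gsta2 averaged 28.4 ± 41.6 and 2.35 ± 0.740 CPM, with 76.4 in labelled-null SAL replicate 3, and its near copy Gm10639 averaged 20.7 ± 30.9 and 1.36 ± 0.748. The log2 fold changes were -1.88 ± 0.61 for Serpinb3a, 0.18 ± 0.49 for Serpinb3b, -0.56 ± 0.70 for Serpinb3c and -0.995 ± 0.78 for Serpinb3d. Adjusted over the list alone, 1 of these 4, Serpinb3a, passed, and 0 over all genes. The groups did not overlap for 10.5% of genes, against 10% by chance.

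Labelled-null skin was compared with wild-type skin under ASP to show what the genotype does in exposed skin. Barrier lipid genes stood higher in labelled-null skin, with a median log2 fold change of 0.43 over 31 genes, 23 of them positive. So did genes of the cornified envelope (0.25 over 44, 31 positive), the cell cycle (0.27 over 38, 28 positive), sebaceous glands (0.25 over 22, 15 positive), immediate early genes (0.32 over 20, 15 positive) and hair (0.70 over 13, 11 positive). Type 17 and antimicrobial genes (0.30 over 14, 8 positive) and clade B serpins other than Serpinb3 (0.11 over 15, 8 positive) passed in the higher direction, with members that went both ways, and mast cell markers stood lower (-0.70 over 11, 1 positive). These 9 of 29 lists passed camera at its preset correlation. The barrier lipid, mast cell, cell cycle, sebaceous and immediate early lists had adjusted p = 3.03e-06, 0.00154, 0.00238, 0.00359 and 0.0115 in that order, and adjusted p = 0.403 with an estimated correlation. The cornified envelope list had adjusted p = 0.000293, and adjusted p = 0.623 with an estimated correlation. The hair list had adjusted p = 0.0218, and adjusted p = 0.560 with an estimated correlation. The type 17 list had adjusted p = 0.0235, and adjusted p = 0.453 with an estimated correlation. The clade B serpin list had adjusted p = 0.0280, and adjusted p = 0.432 with an estimated correlation. The sphingomyelinase Smpd1 averaged 26.9 and 44.5 CPM in wild type and labelled-null (0.73 ± 0.29 SE), and the ceramide synthase Cers4 27.7 and 48.3. Hornerin, Hrnr, a filaggrin-like protein of the envelope, averaged 1966 and 4388 CPM (1.16 ± 0.44), the suprabasal keratin Krt1 916 and 1927, Calml3 14.0 and 29.4 and the crosslinking transglutaminase Tgm1 20.8 and 32.5. In sebaceous glands the fatty acid elongases Elovl3 and Elovl5 averaged 7.07 and 17.2 and 44.2 and 68.8 CPM, Soat1 63.2 and 96.9 and Far2 117 and 179. Mcm3 of the replicative helicase averaged 4.54 and 11.2 CPM, Kif2c 1.93 and 4.11, Top2a 66.3 and 94.1 and Ccna2 27.4 and 43.2.

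Mast cell genes under ASP included Ms4a2, a chain of the IgE receptor, at 8.05 and 1.21 CPM in wild type and labelled-null (-2.73 ± 0.90). The carboxypeptidase Cpa3 averaged 97.1 and 49.1 (-0.98 ± 0.38), the tryptase Tpsab1 4.13 and 1.66 and the receptor Kit 14.1 and 8.44. Lcn2, an antimicrobial protein that binds siderophores, averaged 0.596 and 6.21 CPM (3.28 ± 0.92) and was the 1 type 17 gene that passed adjusted over the list alone. Il1f8 (IL-36 beta) averaged 5.29 and 9.16, the defensin Defb1 12.7 and 6.21 and Wfdc5 20.1 and 31.3. Serpinb11 averaged 1.51 and 9.52 CPM (2.61 ± 0.58) and was the 1 clade B serpin that passed adjusted over the list alone. Serpinb12 averaged 2.22 and 7.61, Serpinb13 0.150 and 1.64 and Serpinb9 12.6 and 7.53. Fos averaged 5.07 and 13.9 CPM, Nr4a1 5.36 and 9.93, Ier3 2.42 and 5.25 and the chaperone Hsp90aa1 350.3 and 229. The hair genes Krtap3-3, Krtap3-2, Msx1 and Wnt11 averaged 0.268, 1.15, 0.309 and 0.516 CPM in wild type and 0.827, 2.80, 0.942 and 1.17 in labelled-null skin. The other 7 lists had 0 genes adjusted over the list alone, and all 9 had 0 over all genes. The barrier lipid call held at the preset correlation in 6 fits that each left out 1 library, with a highest adjusted p of 0.0342. Those fits did not vary the correlation, and the call was lost with an estimated one (adjusted p = 0.403) and with fry (0.539). Leaving out wild-type ASP replicate 2 ended the calls for clade B serpin (adjusted p = 0.126), cornified envelope (0.150), cell cycle (0.166), mast cell (0.166), hair (0.166) and immediate early (0.212). Without wild-type ASP replicate 1, the calls for clade B serpin (adjusted p = 0.344), type 17 (0.542) and sebaceous (0.344) ended. The calls for clade B serpin (adjusted p = 0.141) and type 17 (0.0558) ended without labelled-null ASP replicate 3. Leaving out wild-type ASP replicate 3 ended the calls for type 17 (adjusted p = 0.211) and hair (0.402). Without labelled-null ASP replicate 1, the calls for hair (adjusted p = 0.522) and immediate early (0.0556) ended. The call for type 17 (adjusted p = 0.0657) ended without labelled-null ASP replicate 2. Without both libraries farthest from the rest, the type 17 list had adjusted p = 0.218 and the hair list 0.429.

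Over all genes under ASP, edgeR called 0 higher and 0 lower in labelled-null skin, with 139 and 332 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. DESeq2 called 2 higher (Serpinb11 and Cyp2g1) and 3 lower (Gpnmb and, named after their values were seen, Acsf3 and Gm15093), and limma-voom called 0 and 0. The 5 genes with the smallest p did not pass in edgeR. Gpnmb, a glycoprotein of melanosomes and macrophages, averaged 53.8 ± 27.5 and 12.6 ± 1.07 CPM in wild type and labelled-null (SD, n = 3, -2.10 ± 0.43 SE), and Serpinb11 averaged 1.51 ± 1.10 and 9.52 ± 1.07. The carboxylesterase Ces4a averaged 10.5 ± 1.42 and 37.6 ± 18.8 CPM (1.84 ± 0.41) and the cytochrome P450 gene Cyp2g1 5.74 ± 4.49 and 41.0 ± 30.5 (2.84 ± 0.69). The potassium channel gene Kcna6 averaged 31.5 ± 50.7 and 1.25 ± 0.562, with 90.1 CPM in wild-type ASP replicate 3. Serpinb3a had a log2 fold change of 1.31 ± 0.63, Serpinb3b -0.95 ± 0.48, Serpinb3c -1.04 ± 0.69 and Serpinb3d 2.68 ± 0.91, and 1 of the 4, Serpinb3d, passed adjusted over the list alone. The groups did not overlap for 7.62% of genes, against 10% by chance.

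Under SAL, labelled-null skin was compared with wild-type skin to show what the genotype does without the extract. Monocyte and macrophage markers stood higher in labelled-null skin, with a median log2 fold change of 0.64 over 24 genes, 21 of them positive. Dendritic cell markers (0.44 over 22, 19 positive), neutrophil markers (0.76 over 8, 8 positive), type 2 genes (0.34 over 24, 18 positive) and type 17 genes (0.39 over 14, 11 positive) stood higher too. Among epidermal lists, the cornified envelope (0.34 over 44, 39 positive), epidermal stress (0.41 over 28, 19 positive), barrier lipid (0.27 over 31, 24 positive) and sebaceous (0.27 over 22, 19 positive) genes stood higher. The Serpinb3 paralogs passed with members split, 2 of 4 positive and 2 negative. Endothelial (-0.39 over 18, 5 positive) and skeletal muscle genes (-0.28 over 29, 6 positive) stood lower. These 12 of 29 lists passed camera at its preset correlation. The correlation estimated for each of them was above the preset 0.01, from 0.0374 (neutrophil) to 0.395 (cornified envelope), so the preset p-values may be too small. The monocyte, type 2, sebaceous, dendritic cell and neutrophil lists had adjusted p = 4.06e-08, 0.00187, 0.00187, 0.00404 and 0.00887 in that order, and adjusted p = 0.246 with an estimated correlation. The cornified envelope list had adjusted p = 0.000251, and adjusted p = 0.580 with an estimated correlation. The epidermal stress list had adjusted p = 0.00345, and adjusted p = 0.295 with an estimated correlation. The endothelial and Serpinb3 paralog lists had adjusted p = 0.00358 and 0.0115 in that order, and adjusted p = 0.289 with an estimated correlation. The type 17 list had adjusted p = 0.00887, and adjusted p = 0.334 with an estimated correlation. The barrier lipid list had adjusted p = 0.00887, and adjusted p = 0.547 with an estimated correlation. The muscle list had adjusted p = 0.0430, and adjusted p = 0.702 with an estimated correlation. C1qc, a chain of complement C1q made by macrophages, averaged 41.3 and 108 CPM in wild type and labelled-null (1.38 ± 0.30 SE). The lysozymes Lyz1 and Lyz2, which share reads, averaged 71.2 and 167 and 269.9 and 592, and the IgG receptor Fcgr1 1.18 and 4.67. Ccl24 averaged 0.184 and 1.77 CPM (3.23 ± 0.98), its receptor Ccr3 1.55 and 8.02, Ccl22 3.18 and 9.91 and Il1rl1 4.94 and 11.7. The class II gene H2-Ab1 averaged 69.4 and 116 CPM, Clec9a 1.18 and 4.01, Cd24a 103 and 153 and H2-Eb1 19.97 and 35.4. Retnlg, a gene of neutrophils, averaged 0.236 and 2.68 CPM, the chemokine receptor Cxcr2 83.5 and 110.1 and Hcar2 14.3 and 20.2.

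Il1f6 (IL-36 alpha), a keratinocyte cytokine, averaged 2.91 and 13.3 CPM in wild type and labelled-null under SAL (2.20 ± 0.63), Wfdc21 2.36 and 10.8, S100a8 1.02 and 3.32 and Il1f8 8.19 and 12.7. The stefins Stfa3 and Stfa2 averaged 2.96 and 44.3 and 0.340 and 2.61, Sprr2d 0.535 and 2.36 and the urokinase gene Plau 30.4 and 15.8. Most of the Stfa3 mean in labelled-null comes from SAL replicate 1, as given above, though the other replicates there also exceeded the wild-type mean. The kallikrein Klk8 averaged 7.41 and 27.2 CPM, Cnfn (cornifelin) 87.5 and 161, Calml3 18.4 and 31.8 and Lce1a2 70.3 and 103. The fatty acid transporter Slc27a4 averaged 16.7 and 34.4 CPM (1.04 ± 0.37), the elongase Elovl7 47.0 and 79.2 and the lipase Lipk 13.1 and 19.0. Awat2 and Awat1, which make the wax esters of sebum, averaged 3.02 and 11.9 and 4.44 and 11.4 CPM, Dgat2l6 2.83 and 7.43 and Pm20d1 7.13 and 3.42. In endothelium Flt1 averaged 34.2 and 16.8 CPM, VE-cadherin (Cdh5) 65.0 and 29.6, Robo4 11.1 and 5.60 and Vcam1 2.92 and 6.67. In muscle Pygm averaged 235 and 104 CPM, Mybpc2 243 and 127, Myh7 4.90 and 1.67 and Tnnt1 4.37 and 13.4. Adjusted over the list alone, 3 Serpinb3 paralogs passed (Serpinb3a and Serpinb3d higher, Serpinb3b lower), along with 1 monocyte gene (C1qc), 1 type 17 gene (Il1f6) and 1 stress gene (Stfa3). The other 8 lists had 0 genes adjusted over the list alone, and all 12 had 0 over all genes.

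The monocyte and macrophage call under SAL held at the preset correlation in 6 fits that each left out 1 library, with a highest adjusted p of 0.00106. Those fits did not vary the correlation, and the call was lost with an estimated one (adjusted p = 0.246) and with fry (0.314). Leaving out labelled-null SAL replicate 2 ended the calls for Serpinb3 paralog (adjusted p = 0.127), type 2 (0.0660), type 17 (0.229), epidermal stress (0.166), cornified envelope (0.824), barrier lipid (0.824), dendritic cell (0.142), muscle (0.130) and endothelial (0.229). Without wild-type SAL replicate 3, the calls for Serpinb3 paralog (adjusted p = 0.592), type 17 (0.473), epidermal stress (0.178), barrier lipid (0.0906), neutrophil (0.331) and muscle (0.592, with the direction turned) ended. The calls for type 17 (adjusted p = 0.104), epidermal stress (0.103), barrier lipid (0.0730), neutrophil (0.203), dendritic cell (0.0730) and muscle (0.104) ended without labelled-null SAL replicate 3. Leaving out wild-type SAL replicate 1 ended the calls for dendritic cell (adjusted p = 0.0945) and muscle (0.812). Without wild-type SAL replicate 2, the call for sebaceous (adjusted p = 0.146) ended. The call for muscle (adjusted p = 0.0868) ended without labelled-null SAL replicate 1. With the replicate number as a block, the muscle call had adjusted p = 0.0727. Without both libraries farthest from the rest, the muscle list had adjusted p = 0.103. Over all genes, edgeR called 0 higher and 0 lower in labelled-null skin under SAL, with 339 and 331 at an unadjusted p under 0.05 and a smallest adjusted p of 0.354. DESeq2 called 6 higher and 0 lower, and limma-voom called 0 and 0. The 5 genes with the smallest p in edgeR, which did not pass there, were all called by DESeq2, together with Gm15093, named after its values were seen. They were Serpinb11 (0.715 ± 0.382 and 8.17 ± 2.65 CPM in wild type and labelled-null, SD, n = 3, log2 fold change 3.52 ± 0.62 SE), Serpinb3a (3.66 ± 0.67), C1qc, Gsta2 and Cyp2g1. Serpinb11 lies on chromosome 1 from 107362314 to 107380475. Cyp2g1 averaged 6.21 ± 2.18 and 53.0 ± 20.9 CPM (3.09 ± 0.69) and Gsta2 1.55 ± 0.876 and 28.4 ± 41.6, with 76.4 in labelled-null SAL replicate 3 and 3.04 and 5.86 in replicates 1 and 2. Serpinb3d had a log2 fold change of 3.45 ± 0.89, Serpinb3b -1.81 ± 0.50 and Serpinb3c -0.60 ± 0.69. The groups did not overlap for 8.06% of genes, against 10% by chance.

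The interaction asks whether the response to ASP differs between labelled-null and wild-type skin. Dendritic and Langerhans cell markers had a lower response in labelled-null skin, with a median log2 difference of -0.76 over 22 genes, 4 of them positive. Monocyte and macrophage markers (-0.50 over 24, 7 positive) and B and plasma cell markers (-0.88 over 4, 0 positive) had a lower response too, and hair (1.43 over 13, 10 positive) and skeletal muscle genes (0.56 over 29, 22 positive) had a higher one. These 5 of 29 lists passed camera at its preset correlation. The dendritic cell and B cell lists had adjusted p = 0.00283 and 0.0227 in that order, and adjusted p = 0.248 with an estimated correlation. The hair list had adjusted p = 0.00907, and adjusted p = 0.778 with an estimated correlation. The monocyte and muscle lists had each adjusted p = 0.0235, and adjusted p = 0.813 with an estimated correlation. H2-Ab1 averaged 69.4 and 88.6 CPM under SAL and ASP in wild type, and 116 and 66.3 in labelled-null skin (log2 difference -1.16 ± 0.43 SE). Cd83 averaged 1.29 and 6.87 in wild type and 2.40 and 1.77 in labelled-null skin (-2.83 ± 1.13). The difference was -3.63 ± 1.45 for Batf3 and -2.63 ± 1.10 for Clec9a. C1qc averaged 41.3 and 48.6 CPM in wild type and 108 and 55.6 in labelled-null skin (-1.19 ± 0.41). The difference was -1.26 ± 0.59 for Lyz2, -1.15 ± 0.57 for Lyz1 and -1.66 ± 1.01 for Ms4a7. Tnfrsf13c had -3.81 ± 1.08 and was the 1 B cell gene that passed adjusted over the list alone, beside the complement receptor Cr2 (-1.22 ± 1.00), Jchain (-0.54 ± 0.54) and Fcer2a (-0.31 ± 0.65). In the hair list Tchh had 5.06 ± 1.78, Krt27 4.18 ± 1.64, Krtap3-3 3.43 ± 1.66 and Krtap3-2 2.41 ± 1.45. The Tchh value rests on wild-type SAL replicate 1, at 165 CPM of the unscaled total against 5.88 or less in every other library. In muscle Pygm had 1.95 ± 0.72, Mybpc2 1.53 ± 0.57, Myh7 2.28 ± 1.08 and Casq1 1.35 ± 0.71. The other 4 lists had 0 genes adjusted over the list alone, and all 5 had 0 over all genes.

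At camera's preset correlation, the dendritic cell call for the interaction held in 12 fits that each left out 1 library, with a highest adjusted p of 0.0459. Those fits did not vary the correlation. Over all 12 libraries the call was lost with an estimated correlation (adjusted p = 0.248) and with fry (adjusted p = 0.446). Leaving out wild-type SAL replicate 1 ended the calls for monocyte (adjusted p = 0.262), B cell (0.262), hair (0.413) and muscle (0.382). Without wild-type ASP replicate 2, the calls for monocyte (adjusted p = 0.564), B cell (0.295) and muscle (0.295) ended. The calls for monocyte (adjusted p = 0.133), B cell (0.102) and muscle (0.0514) ended without labelled-null SAL replicate 2. Leaving out labelled-null SAL replicate 3 ended the calls for monocyte (adjusted p = 0.316), B cell (0.316) and muscle (0.0596). Without labelled-null ASP replicate 2, the calls for monocyte (adjusted p = 0.218) and B cell (0.413) ended. The calls for B cell (adjusted p = 0.254) and muscle (0.649) ended without wild-type SAL replicate 3. Leaving out wild-type SAL replicate 2 ended the call for B cell (adjusted p = 0.212). Without wild-type ASP replicate 1, the call for B cell (adjusted p = 0.160) ended. The call for B cell (adjusted p = 0.174) ended without wild-type ASP replicate 3. Leaving out labelled-null SAL replicate 1 ended the call for B cell (adjusted p = 0.0589). Without labelled-null ASP replicate 1, the call for B cell (adjusted p = 0.291) ended. The call for muscle (adjusted p = 0.130) ended without labelled-null ASP replicate 3. The B cell call was kept only without labelled-null ASP replicate 3 (adjusted p = 0.0452) among the 12 fits that each left out 1 library, and without both libraries farthest from the rest its adjusted p was 0.0864.

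Over all genes, edgeR called 0 with a higher and 0 with a lower response in labelled-null skin, with 227 and 358 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. DESeq2 called 0 higher and 1 lower (Gm15093), and limma-voom called 0 and 0. The 5 genes with the smallest p did not pass in edgeR. Nlrc4, an inflammasome sensor, stood at 25.4 CPM in labelled-null SAL replicate 1 and 14.9 in wild-type ASP replicate 3, and at 1.795 or less in the other 10 libraries. Gm15093, a gene model, was at 0 in every wild-type SAL and labelled-null ASP library, so no fold is given. It stood at 16.6 CPM in labelled-null SAL replicate 1 and at 3.73 and 1.59 in wild-type ASP replicates 2 and 3, and at 0 in the other 9 libraries, so its DESeq2 calls in all 5 comparisons rest on these 3 libraries. Ms4a6b averaged 4.12 ± 2.67 and 12.3 ± 6.23 CPM under SAL and ASP in wild type and 21.1 ± 20.8 and 6.37 ± 1.79 in labelled-null skin (SD, n = 3, -3.30 ± 0.90 SE). Labelled-null SAL replicate 1 stood at 44.9, against 6.46 and 11.96 in replicates 2 and 3. Vmn2r46, a vomeronasal receptor gene with many similar copies, had -4.76 ± 1.09. Reep2 had 6.42 ± 1.75, with 14.3 CPM in wild-type SAL replicate 2 and 1.27 or less in the other 11 libraries. The Serpinb3 paralogs had -2.35 ± 0.90 (Serpinb3a), 0.86 ± 0.68 (Serpinb3b), -0.44 ± 0.97 (Serpinb3c) and -0.77 ± 1.33 (Serpinb3d). Across the 15341 genes, which are not independent replicates, the 2 responses to ASP had a Pearson correlation of 0.0131 and a Spearman correlation of 0.0729, with the same sign for 52.6% of genes. The Pearson value ran from -0.181 to 0.0709 over 12 fits that each left out 1 library, was -0.120 with no filter on low counts, and was 0.134 without both libraries farthest from the rest.

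Averaged over both treatments, a comparison added after seeing the data, Serpinb11 was higher in labelled-null skin. It averaged 8.84 ± 1.95 CPM in labelled-null and 1.12 ± 0.859 in wild type (SD, n = 6, log2 fold change 3.06 ± 0.42 SE, edgeR adjusted p = 0.0257) and was higher in 6 of 6 labelled-null libraries than in any wild-type library. The genotypes did not overlap for 31 of 15341 genes (0.202%). Full separation has a two-sided exact permutation p of 0.00217 over 924 splits, so that share is near chance. Serpinb11 was the 1 gene that edgeR called higher, with 0 lower and 573 at an unadjusted p under 0.05. Its log2 fold change stayed between 2.88 and 3.42 over 12 fits that each left out 1 library, and its adjusted p was under 0.05 in 4 of them. Leaving out wild-type SAL replicates 1, 2 or 3 gave adjusted p = 0.187, 0.0529, 0.166, and leaving out labelled-null SAL replicates 1 or 3 gave 0.105 and 0.120. Leaving out labelled-null ASP replicates 1, 2 or 3 gave 0.0949, 0.117, 0.0978, the replicate number as a block 0.0633, and leaving out both libraries farthest from the rest 0.0761. Cyp2g1 (2.97 ± 0.49, adjusted p = 0.104), Serpinb3a (2.48 ± 0.46, 0.258), Gpnmb (-1.58 ± 0.30, 0.261) and Serpinb3d (3.06 ± 0.64, 0.530) did not pass in edgeR. DESeq2 called 6 genes higher and 2 lower, and limma-voom 2 and 1. Averaged over both genotypes, also added after seeing the data, ASP against SAL had 0 genes higher and 0 lower in edgeR, with 865 at an unadjusted p under 0.05, and 0 in DESeq2 and limma-voom.

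The remaining lists passed camera in none of the 5 planned comparisons, and the comparison with each list's smallest adjusted p is given. Hair follicle stem cell genes had a median log2 fold change of -0.25 over 20 genes for ASP in wild type (adjusted p = 0.0504), and eosinophil and basophil markers 1.61 over 5 (0.0545). Tight junction genes had 0.19 over 27 (0.0606), melanocyte markers -0.26 over 9 (0.0661) and interferon genes 0.16 over 37 (0.0815) for labelled-null against wild type under ASP. Fibroblast and matrix genes had -0.09 over 28 (0.455) and proinflammatory cytokines -0.29 over 25 (0.607) in the same comparison. Proteases and their inhibitors had 0.21 over 32 for labelled-null against wild type under SAL (0.0828). T cell and innate lymphoid markers had -0.04 over 20 for the interaction (0.425).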

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

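The tests of Mup read sharing, of exchanged genotype labels, of the paralog sum, and of other splits of the samples were chosen only after the result was seen, except that the splits of labelled-null against wild type over both treatments were planned before their counts were seen, though after Serpinb11 stood out in the planned comparisons. In all, 5 lists stand out because they passed camera at its preset correlation for the interaction. The interaction shares its libraries with the other planned comparisons, so these calls are not separate from theirs. With an estimated correlation or directional fry, 0 lists passed. Dendritic and Langerhans cell markers had a median log2 difference of -0.76 (adjusted p = 0.00283, and adjusted p = 0.248 with an estimated correlation). Hair genes had 1.43 (adjusted p = 0.00907, and adjusted p = 0.778 with an estimated correlation). B and plasma cell markers had -0.88 (adjusted p = 0.0227, and adjusted p = 0.248 with an estimated correlation). Monocyte and macrophage markers had -0.50 and skeletal muscle genes 0.56 (each adjusted p = 0.0235, and adjusted p = 0.813 with an estimated correlation).

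Serpinb3a, Serpinb3d and Serpinb11 were higher and Serpinb3b lower in the labelled-null libraries. Reads shared with the Serpinb3 paralogs are argued against for Serpinb11, since 0% of its 50-base stretches occur in them without a mismatch. Stretches shared with other genes were not searched. An exchange of genotype labels between libraries was tested without a decision and stays open: over the 5 Serpinb genes, 11 values of single libraries lay nearer the median of the other genotype, at most 2 of 5 in any library and 0 of them for Serpinb11, a gene picked from these data. Reads assigned to another of the 4 Serpinb3 paralogs were tested without a decision and stay open for their own differences. The sum of the 4 gave an exact p of 0.310, which supports nothing, and Serpinb3b was lower where Serpinb3a was higher, while 4.97% to 14.3% of a paralog's 50-base stretches occur in another. A flanking interval from the strain of the targeted allele cannot be told apart from an effect of the allele itself. The 1 called gene within 10 Mb is Serpinb11 itself, so its one-sided Fisher exact p of 0.00196 restates the difference and supports neither, and without the 5 Serpinb genes 0 of 25 genes there were at an unadjusted p under 0.05 against 3.72% elsewhere (p = 1, odds ratio up to 4.13). A biological effect of the genotype, and a wrong genotype label on all 6 libraries, stay open and were not tested.

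No gene passed in edgeR for ASP against SAL in either genotype. A spread widened by the 2 libraries farthest from the rest was tested without a decision and stays open. With both left out, 1 gene passed over the 2 comparisons (Snrpd2 in wild type, named after its values were seen, adjusted p = 0.0371). That count decides nothing, since leaving them out also took 1 library from each comparison, so a smaller spread came with fewer replicates. Wild-type ASP replicate 2, with a median correlation with the others of 0.902, stayed in. A weak or absent biological response stays open and was not tested.

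Mup genes took 8.43% to 39.0% of the counts in skin. RNA from liver is argued against, since liver transcripts reached at most 0.0105% of the Mup level in any library. Reads shared between near-identical copies are consistent with the median correlation of 0.9995 between Mup genes over the 12 libraries. No biological explanation was tested.

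Other splits of the samples were counted for each comparison. For the 4 comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05, with 0 genes for the real split and 0 for the highest other in ASP against SAL in wild type, in ASP against SAL in labelled-null, and between genotypes under ASP and under SAL. For the interaction and for ASP against SAL over both genotypes the real split gave 0 and 0 genes, a count that all 60 splits reach by construction, so these splits decide nothing. The highest other gave 15 and 0 in that order. In the interaction 3 of 59 other splits gave any genes, which may reflect a structure of the samples or single libraries and was not tested. For labelled-null against wild type over both treatments, 2 of 60 splits gave as many called genes as the real 1 and the highest other gave 1, but the comparison was added after Serpinb11, its 1 called gene, had been seen to differ, so no exclusion of chance is drawn from it. The call was lost in 8 of 12 fits that left out 1 library. At an unadjusted p under 0.05, 48 of 60 splits gave as many genes as the real 573 (median of the others 741). For the 4 comparisons of 3 against 3 libraries, in the order above, the real counts were 727, 693, 471 and 670. As many came from 7, 4, 9 and 7 of 10 splits, with medians of the others of 1213, 641, 703 and 797.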

How the results depend on the processing

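The settings without both libraries farthest from the rest (wild-type ASP replicate 3 and labelled-null SAL replicate 1), those without Mup genes and unnamed IDs, and all settings of the averaged comparisons were chosen only after the result was seen. Where a value changed, the cause was not tested. With DESeq2 the count of 0 genes became 1 higher for ASP against SAL in wild type, 1 lower for ASP against SAL in wild type, 2 lower for ASP against SAL in labelled-null, 2 higher for labelled-null against wild type under ASP, 3 lower for labelled-null against wild type under ASP, 6 higher for labelled-null against wild type under SAL and 1 lower for the interaction. Without both libraries farthest from the rest it became 1 higher for ASP against SAL in wild type. Scaling, filters, robust off, the replicate block, limma-voom and each library left out gave 0 genes in all 5 planned comparisons. The fit on only the 6 libraries compared, which does not apply to the interaction, gave 0 genes in the other planned comparisons. Averaged over treatments, labelled-null against wild type had 1 gene higher, and 0 with the replicate block, 6 with DESeq2, 2 with limma-voom, 0 without both libraries farthest from the rest, and 0 to 2 over the fits that left out 1 library. The 0 genes lower became 1 with no filter on low counts, 2 with DESeq2 and 1 with limma-voom.

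For ASP against SAL in wild type, the 6 lists called became 0 with the estimated correlation, 0 with fry and 0 to 9 over the fits that left out 1 library. The estimated correlation gave adjusted p = 0.506 (type 2, dendritic cell, hair, immediate early), 0.650 (monocyte) and 0.876 (muscle). Fry gave 0.681 (type 2, dendritic cell, hair, immediate early), 0.811 (monocyte) and 0.918 (muscle). Leaving out 1 library gave 0.000758 to 0.297 (type 2), 0.000221 to 0.297 (monocyte), 0.00207 to 0.131 (dendritic cell), 1.16e-11 to 0.113 (hair), 2.52e-13 to 0.705 (muscle) and 0.00479 to 0.174 (immediate early). Leaving out both libraries farthest from the rest gave 0.0660 (type 2) and 0.113 (dendritic cell).

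For ASP against SAL in labelled-null, the 3 lists called became 0 with the estimated correlation, 0 with fry and 1 to 9 over the fits that left out 1 library, and 7 without both libraries farthest from the rest. The estimated correlation gave adjusted p = 0.699 (epidermal stress) and 0.963 (adipocyte, red blood cell). Fry gave 0.810 (epidermal stress) and 0.967 (adipocyte, red blood cell). Leaving out 1 library gave 2.05e-06 to 0.117 (epidermal stress), 0.00160 to 0.919 (adipocyte) and 0.000917 to 0.972 (red blood cell). The replicate block gave 0.0793 (red blood cell). Leaving out both libraries farthest from the rest gave 0.887 (adipocyte).

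For labelled-null against wild type under ASP, the 9 lists called became 0 with the estimated correlation, 0 with fry and 4 to 13 over the fits that left out 1 library. The estimated correlation gave adjusted p = 0.432 (clade B serpin), 0.453 (type 17), 0.623 (cornified envelope), 0.403 (barrier lipid, cell cycle, mast cell, sebaceous, immediate early) and 0.560 (hair). Fry gave 0.591 (clade B serpin, immediate early), 0.706 (type 17), 0.794 (cornified envelope, hair), 0.539 (barrier lipid, mast cell) and 0.547 (cell cycle, sebaceous). Leaving out 1 library gave 0.0122 to 0.344 (clade B serpin), 0.00899 to 0.542 (type 17), 2.40e-06 to 0.150 (cornified envelope), 0.000488 to 0.166 (cell cycle), 2.81e-05 to 0.166 (mast cell), 0.00271 to 0.522 (hair), 0.000337 to 0.344 (sebaceous) and 0.00271 to 0.212 (immediate early). Leaving out both libraries farthest from the rest gave 0.218 (type 17) and 0.429 (hair).

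For labelled-null against wild type under SAL, the 12 lists called became 0 with the estimated correlation, 0 with fry and 3 to 18 over the fits that left out 1 library. The estimated correlation gave adjusted p = 0.289 (Serpinb3 paralog, endothelial), 0.246 (type 2, neutrophil, monocyte, dendritic cell, sebaceous), 0.334 (type 17), 0.295 (epidermal stress), 0.580 (cornified envelope), 0.547 (barrier lipid) and 0.702 (muscle). Fry gave 0.314 (Serpinb3 paralog, neutrophil, monocyte, dendritic cell, sebaceous), 0.329 (type 2), 0.549 (type 17, epidermal stress), 0.717 (cornified envelope), 0.624 (barrier lipid), 0.853 (muscle) and 0.332 (endothelial). Leaving out 1 library gave 0.00716 to 0.592 (Serpinb3 paralog), 3.26e-05 to 0.0660 (type 2), 0.00141 to 0.473 (type 17), 7.10e-08 to 0.178 (epidermal stress), 2.11e-13 to 0.824 (cornified envelope), 6.30e-06 to 0.824 (barrier lipid), 0.00277 to 0.331 (neutrophil), 0.000227 to 0.142 (dendritic cell), 0.000186 to 0.146 (sebaceous), 8.11e-13 to 0.812 (muscle) and 4.92e-05 to 0.229 (endothelial). The replicate block gave 0.0727 (muscle). Leaving out both libraries farthest from the rest gave 0.103 (muscle).

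For the interaction, the 5 lists called became 0 with the estimated correlation, 0 with fry and 2 to 9 over the fits that left out 1 library, and 8 without both libraries farthest from the rest. The estimated correlation gave adjusted p = 0.813 (monocyte, muscle), 0.248 (B cell, dendritic cell) and 0.778 (hair). Fry gave 0.911 (monocyte, hair, muscle), 0.199 (B cell) and 0.446 (dendritic cell). Leaving out 1 library gave 6.25e-05 to 0.564 (monocyte), 0.0452 to 0.413 (B cell), 9.13e-08 to 0.413 (hair) and 2.99e-10 to 0.649 (muscle). Leaving out both libraries farthest from the rest gave 0.0864 (B cell).

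These fry values are directional. Regardless of direction fry passed 2 lists for labelled-null against wild type under SAL, Serpinb3 paralog and clade B serpin (each adjusted p = 0.0285), and 0 in the other 4 planned comparisons. The correlation of responses, 0.0131, became -0.120 with no filter on low counts, 0.134 without both libraries farthest from the rest and -0.181 to 0.0709 over the fits that left out 1 library (SD 0.0682). The 184 values of genes under the naming rule had 3267 alternatives, of which 19 moved a value past the threshold, 10 took one back under it and 0 reversed a called value. Signs differed in 15 alternatives of values not called. Changes of 2 times were mostly below what this depth and spread could show, and larger changes could be missed too.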

Other observations

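The averaged comparisons below were chosen only after the results of the planned comparisons were seen, and fits that left out single libraries were not run for their lists. Over both treatments, 15 of 29 lists passed camera at its preset correlation for labelled-null against wild type. The cornified envelope list had adjusted p = 4.92e-08, and adjusted p = 0.281 with an estimated correlation. The barrier lipid, monocyte, sebaceous, type 17, cell cycle, clade B serpin, type 2, immediate early, Serpinb3 paralog and mast cell lists had adjusted p = 6.00e-08, 6.00e-08, 3.64e-06, 0.000258, 0.00116, 0.00379, 0.00962, 0.0105, 0.0116 and 0.0116 in that order, and adjusted p = 0.234 with an estimated correlation. The endothelial list had adjusted p = 0.00962, and adjusted p = 0.280 with an estimated correlation. The epidermal stress list had adjusted p = 0.0116, and adjusted p = 0.316 with an estimated correlation. The tight junction list had adjusted p = 0.0411, and adjusted p = 0.708 with an estimated correlation. The interferon list had adjusted p = 0.0490, and adjusted p = 0.517 with an estimated correlation. Fry regardless of direction passed the Serpinb3 paralog (adjusted p = 0.0378) and clade B serpin lists (9.47e-05), and directional fry passed 0. Cornified envelope genes had a median log2 fold change of 0.25 over 44 genes, with Calml3 at 0.92 ± 0.28 SE, Klk8 at 1.10 ± 0.44 and Hrnr at 0.76 ± 0.31. Barrier lipid genes had 0.35 over 31, with the fatty acid transporter Slc27a4 at 0.90 ± 0.26 and Elovl7 at 0.66 ± 0.21. Monocyte and macrophage markers had 0.34 over 24, with C1qc at 0.79 ± 0.21 and C1qb at 0.52 ± 0.21. Type 17 genes had 0.39 over 14, with Lcn2 at 2.17 ± 0.61 and Il1f6 at 1.44 ± 0.44. Mast cell markers had -0.27 over 11, with the carboxypeptidase Cpa3 at -0.61 ± 0.27 and the receptor Mrgprb2 at -0.56 ± 0.32. Endothelial genes had -0.44 over 18, with Cdh5 at -0.87 ± 0.33 and Selp at -0.98 ± 0.55. Tight junction genes had 0.12 over 27, with Cldn12 at -0.64 ± 0.24, and interferon genes 0.12 over 37, with Oas1a at 0.64 ± 0.34.

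Over both genotypes, 5 of 29 lists passed camera at its preset correlation for ASP against SAL. The hair, red blood cell, epidermal stress, immediate early and follicle stem cell lists had adjusted p = 0.00218, 0.00487, 0.0151, 0.0151 and 0.0217 in that order, and adjusted p = 0.844 with an estimated correlation. Hair genes had a median log2 fold change of -0.67 over 13, epidermal stress genes -0.41 over 28, immediate early genes -0.22 over 20 and hair follicle stem cell genes -0.21 over 20. Red blood cell transcripts had 0.83 over 7, with the identical globin pairs again counted separately. Nr4a1 had -1.39 ± 0.32 and Hsph1 -0.98 ± 0.23. Adjusted over the list alone, 2 immediate early genes and 1 hair gene passed, and 0 over all genes. Cyp2g1 ranged from 19.8 to 76.0 CPM in the 6 labelled-null libraries and from 0.560 to 8.70 in the 6 wild-type libraries. It was among the 31 of 15341 genes (0.202%) without overlap between the genotypes.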
